A study of Mus musculus with 2 samples.

How the data were processed

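Chromatin immunoprecipitation sequencing (ChIP-seq) was used to map the genomic sites bound by SATB2, a DNA-binding chromatin organiser, in the cerebral cortex of wild-type C57BL/6J mouse embryos at embryonic day 17.5. Per the labels' protocols, 22 ug of chromatin was precipitated with an antibody against SATB2, and a library from the same tissue made without antibody served as input. The design held 1 ChIP library and 1 input library, so no value below has a replicate. The labels do not say how many embryos were pooled or of which sex.

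The deposited peak list gave each peak's interval and summit on build mm10. The submitters' processing notes name BWA 0.7.17, bedtools 2.29.2 and MACS2 2.2.7, without their roles or order. Duplicate removal, filters on multiply placed reads, on chromosomes or on listed regions, and the control given to the peak caller are not given in the sources used here. The deposited list carried a fold enrichment at each summit, which is a ratio of the ChIP pileup to the local background. It also carried the authors' p-value and q-value for each summit as −log10, and an integer score that equalled 10 times the −log10 q with the decimals dropped. The lowest deposited −log10 q was 3.05, so the list behaved as one limited at a q-value of 0.001. The fold, p-value and q-value are the authors' own values and were used to describe, rank and filter peaks within this list. The input library's own signal was not analysed here.

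The read depth behind each summit was recovered from the deposited fold and p-value. The fold was taken as (pileup + 1) / (background + 1) and the p-value as the upper tail of a Poisson distribution. A whole-number pileup that met both values, within 0.01 in −log10 p, was found for 100% of summits, with a largest gap of 0.000222. A background was counted as the lowest genome-wide level where it lay within 0.001 reads of it. Exact 95% Poisson limits on a pileup cover counting error only, and a peak list keeps only sites that passed its threshold. The total number of reads is not given in the list. Of 4270 backgrounds above the lowest level, 99.9% were whole read counts in windows of 220 bp, 1 kb or 10 kb times a single scale fitted as 0.465, within 0.0003 reads, against 0.7% for the unscaled ChIP library. The background thus came from a separate library, which was taken to be the input, the only other library of the series.

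Gene positions came from the RefSeq gene table of GRCm38.p6, the assembly that mm10 names, and all coordinates are 1-based. The table holds gene starts, ends and biotypes, with no strand, exons, transcripts or sequence. For 110 protein-coding rows the positions referred to unplaced scaffolds or patches under a chromosome's name, and these rows were left out. The remaining 21521 protein-coding genes on chromosomes 1 to 19 and X were used. All gene ends, gene bodies and distances to genes refer to these genes. Intergenic summits lay outside their bodies and over 1 kb from their ends, and may lie in non-coding genes. Because strand was missing, a planned promoter class became a gene end class, defined as a summit within 1 kb of either end of a protein-coding gene. It mixes promoters with the 3' ends of genes. A gene was assigned a summit in its body or within 10 kb on either side, in place of the planned 10 kb upstream. The separation of exons from introns, the GC content at summits, the scan for 22 motifs and the alternatives that need repeat masks or CpG content were not run. Lengths of chromosomes were taken as the span from the first to the last annotated gene, in place of the sequenced bases.

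Shares of summits in a class were compared with 1000 random placements of the same summits within the same chromosome's span. The median folds of gene end summits and other summits were compared with 100000 permutations of the class labels. Each of 21 gene lists, fixed with the other choices before the data were examined, was compared with 10000 random lists of protein-coding genes matched in 20 bins of gene length. All 1910 list entries are genes of the table, counting a gene once per list. All tests were two-sided permutation tests, and p-values of the gene lists were adjusted by the Benjamini-Hochberg method over the 21 lists. The smallest p-values these tests can give were 0.002 for placements, 0.0002 for random lists and 1e-05 for label permutations. They describe positions within this single list and say nothing about variation between animals. Intervals on shares are 95% Wilson intervals and cover counting error only.

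Genes were named by a rule. It took the genes at the 20 summits with the highest fold on the assembled chromosomes, the 10 genes with the most summits, up to 4 members of each list with the highest fold, and Satb2, Bcl11b, Fezf2, Cux2, Tbr1, Unc5c, Dcc and Auts2 whatever their values. Summits on mitochondrial DNA and unplaced scaffolds were left out of the comparisons. Alternatives were a −log10 q of at least 5, the stronger part of the list with a fold at or above the median of 5.41, autosomes only, merged peaks, other overlap rules, other gene windows of 1, 2 and 50 kb, assignment to the nearest gene end and other ways of matching the random lists. The scripts were tested on simulated data. Whole-number pileups were recovered for 100% of 500 simulated summits. These were generated with the same formulas, so this tested the computation and not the formulas. In 8674 simulated positions, a share at gene ends of 22.5% was measured as 23.0%. Simulated lists held 50 genes, over summits placed evenly and without the gathering at gene ends seen in the data. Of 100 lists with a summit added to 20 genes, 100% were called at an unadjusted permutation p under 0.05. Of 100 unchanged lists 8.0% were. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.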

Results

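The binding sites of SATB2, a transcription factor of upper-layer and callosal projection neurons, were mapped by ChIP-seq in the mouse cerebral cortex at E17.5, late in gestation. The study asked which genes SATB2 targets in the developing cortex, with an interest in synapse formation and axon growth. The data comprised 1 SATB2 ChIP library and 1 input library. The peak list held 8719 summits in 7759 regions, of which 834 had more than 1 summit. On chromosomes 1 to 19 and X there were 8674 summits in 7740 regions with a median width of 329 bp (quartiles 257 and 461 bp). The authors' fold enrichment had a median of 5.41 (quartiles 4.73 and 6.42) and reached 29.1. The median summit rested on a pileup of 17 reads (exact 95% Poisson interval 9.90 to 27.2) over a background of 1.96 reads, so single folds were known only to within a wide counting error. For 51.1% of these summits the background lay within 0.001 reads of the lowest level in the list.

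SATB2 summits were spread over all autosomes and were scarce on the X chromosome. Autosomes carried 3.60 summits per Mb, from 2.74 on chromosome 14 to 4.31 on chromosome 11. The X chromosome carried 34 summits, or 0.203 per Mb (exact 95% Poisson interval 0.140 to 0.283). The X-to-autosome ratio was 0.0564 (0.0391 to 0.0788). It was similarly low for summits at gene ends (13 summits, ratio 0.0638), within genes (10 summits, ratio 0.0526) and between genes (11 summits, ratio 0.0526). No summit lay on the Y chromosome. Whether reads or peaks on the sex chromosomes were filtered before deposit is not given in the sources used here. Among X summits, 94.1% had a background within 0.001 reads of the lowest level.

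**Figure D1:**
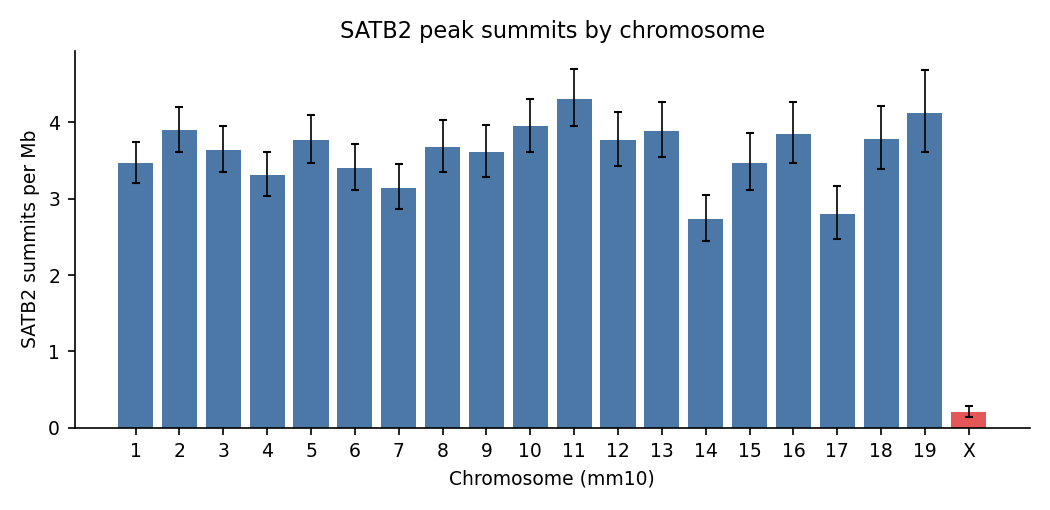
SATB2 summits per Mb (vertical axis) on each mouse chromosome (horizontal axis); bars are counts divided by the annotated span and whiskers are exact 95% Poisson intervals of the 1 library. Autosomes lie between 2.74 and 4.31 summits per Mb and the X chromosome at 0.203.

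SATB2 summits gathered at the ends of protein-coding genes. Of the 8674 summits, 2932 (33.8%, Wilson interval 32.8 to 34.8%) lay within 1 kb of a gene end, against 3.09% ± 0.19 (SD of 1000 random placements), a 10.95-fold excess (permutation p = 0.002, the smallest possible). Gene bodies held 52.7% of summits against 41.0% ± 0.53 at random. The inside of genes more than 1 kb from an end held 31.5% against 39.2% ± 0.52, and intergenic sequence held 34.7% against 57.6% ± 0.51. Positions over 100 kb from any protein-coding gene held 16.9% against 27.3% ± 0.47. Each of these shares lay outside the range of all random placements (permutation p = 0.002, the smallest possible). The table gives no strand, so the class at gene ends mixes transcription start sites with the 3' ends of genes.

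**Figure D2:**
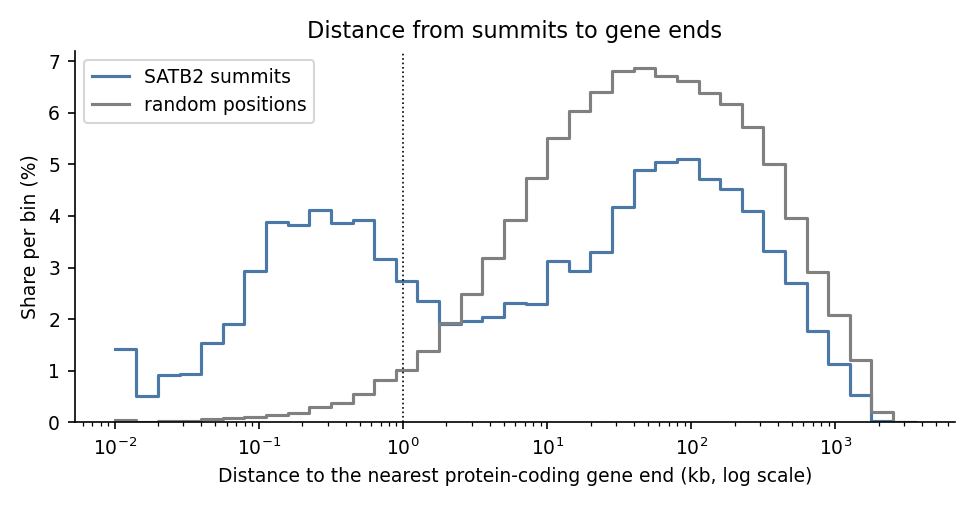
Distance from each SATB2 summit (blue) and from random positions on the same chromosomes (grey) to the nearest protein-coding gene end, in kb on a log axis, as the share of positions per bin; the first bin also holds all shorter distances and the dotted line marks 1 kb. Of the summits 33.8% lie left of the line, against 3.09% of random placements.

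Summits also lay close to each other. For 29.0% of summits, another peak's summit lay within 10 kb, against 6.97% ± 0.37 (SD) for random placements, a 4.16-fold excess (permutation p = 0.002, the smallest possible). Within 1 kb the share was 16.2% against 0.72% ± 0.12. Random placements did not keep the summits' share at gene ends, so these excesses were not set apart from the gathering there. Fold enrichment hardly separated gene end summits from all others, which pooled summits inside genes (median fold 5.41) and intergenic summits (5.72). Summits at gene ends had a median fold of 5.41 and other summits 5.51, a difference of -0.102 (permutation p = 0.0115). The median pileup was 17 reads in both classes, while the median background was 2.32 reads at gene ends and 1.96 reads elsewhere (permutation p = 1e-05, the smallest possible). With the authors' −log10 q in place of the fold, both classes had the same median of 6.86. A difference of 0 fixes the permutation p at 1.0, so this setting does not show that strengths were equal.

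A summit lay in the body or within 10 kb of 5211 of 21521 protein-coding genes (24.2%), and 2816 genes had a summit within 1 kb of an end. Genes with a summit were longer, with a median length of 29819 bp against 14804 bp for genes without. The 10 genes with the most summits were all longer than that median of 29819 bp. Robo2, a receptor for Slit guidance cues, carried 18 summits over 1555468 bp. Dlg2, a postsynaptic scaffold, Gpm6a, a neuronal membrane glycoprotein, and Pcdh9, a protocadherin, carried 17 each. Ptprd, a synaptic receptor phosphatase, carried 16, Lsamp, a cell adhesion protein of the limbic system, 15, and Tenm2, a teneurin, 14. Robo1, Sdccag8 and Sox5 carried 13 each, and Sdccag8 did so over 205779 bp.

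The Satb2 gene itself (chromosome 1, 56793981 to 56981190) held 9 summits, all inside the gene and over 1 kb from its ends. The strongest peak at Satb2 (56949337 to 56949853) had a fold of 10.1 and a pileup of 29 reads (exact 95% Poisson interval 19.4 to 41.6). Auts2, a gene mutated in intellectual disability, held 11 summits, and its strongest (chromosome 5, 131794108 to 131795129) had a fold of 14.5 and 54 reads (40.6 to 70.5). Dcc, a receptor for the guidance cue netrin, held 8 summits inside the gene, with a highest fold of 6.42 on 18 reads. Unc5c, another netrin receptor, had 2 summits, at 0.118 and 0.664 kb from a single end of the gene, with folds of 6.42 and 4.49. Cux2, a marker of upper-layer neurons, had 3 summits, of which the strongest (fold 8.90) lay 9.94 kb outside the gene and within 1 kb of an end of Pheta1; those inside Cux2 had folds of 4.25 and 4.001. Bcl11b, the gene of CTIP2, had 1 summit (chromosome 12, 107928401 to 107928658) 18.1 kb from the nearer gene end, with a fold of 4.24 on 13 reads (6.92 to 22.2). Tbr1 had 1 summit of fold 5.41, 1.36 kb from a gene end. Fezf2 had none within 10 kb, and the nearest lay 47.0 kb away with a fold of 5.07.

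**Figure D3:**
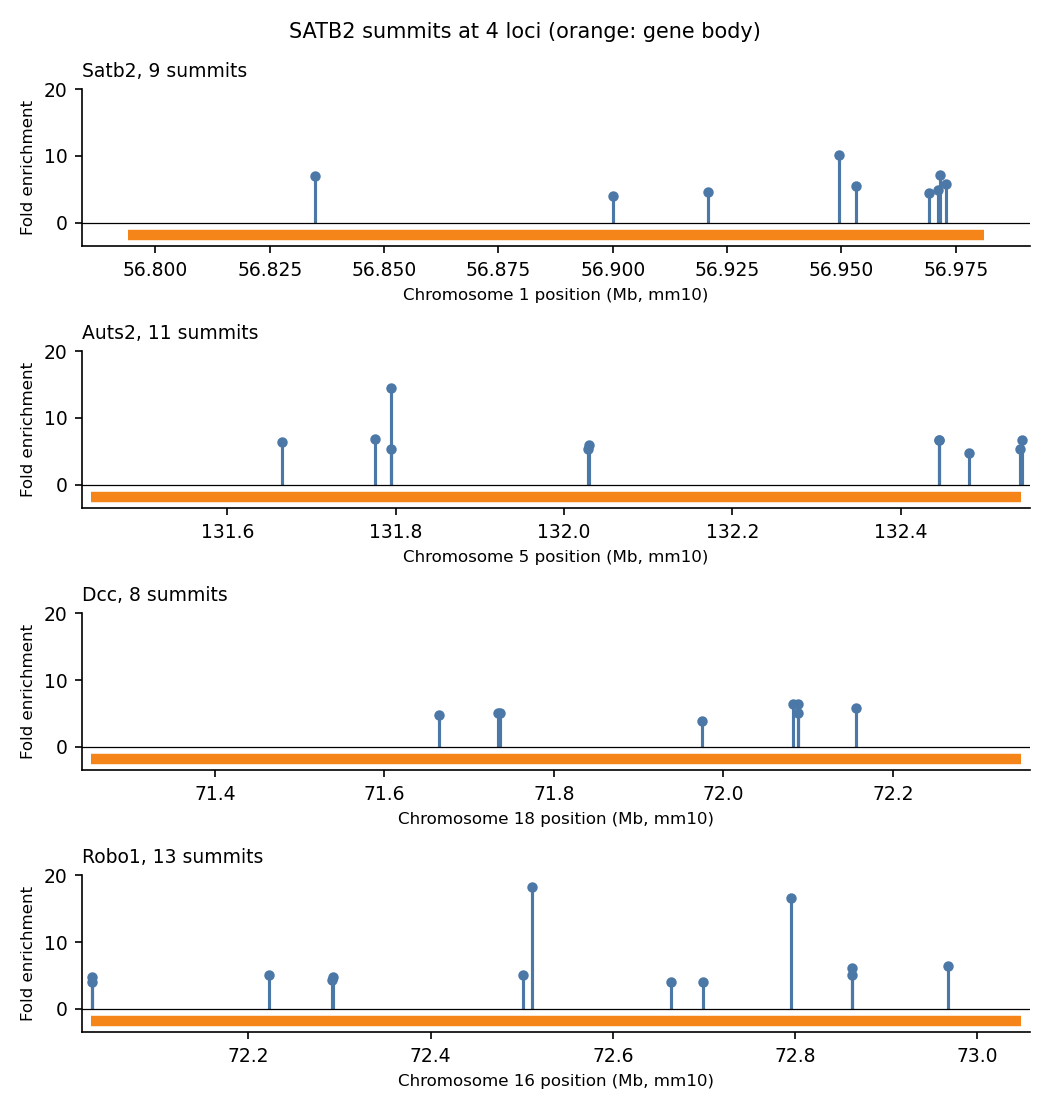
SATB2 summits (blue, height is the authors' fold enrichment) along Satb2, Auts2, Dcc and Robo1 with 10 kb on either side, by mm10 position in Mb; orange bars are gene bodies. Satb2 holds 9 summits, Auts2 11, Dcc 8 and Robo1 13, with highest folds of 10.1, 14.5, 6.42 and 18.3.

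Genes of upper-layer neurons and of axon growth carried SATB2 summits more often than genes of the same length. Of 21 lists, 7 lay above random lists and 1 below, and 13 did not pass (adjusted permutation p of 0.05 or more). Random lists were matched here on gene length alone, not on expression or open chromatin. An excess shared by active genes of any kind was therefore not set apart. By this same measure, 82 of 222 genes of the 5 housekeeping families described below had a summit (1.72 times, adjusted permutation p = 0.000533). Of 29 upper-layer and callosal projection neuron genes, 19 had a summit, 1.88 times the count of length-matched random lists (adjusted permutation p = 0.00300). The strongest members were the corepressor gene Tle3 (fold 15.6), Satb2 (10.1), Cux2 (8.90, the summit near Pheta1) and Inhba (7.52). Of 40 axon growth and cytoskeleton genes, 27 had a summit (1.99 times, adjusted permutation p = 0.00084, from the smallest unadjusted p possible). They included Map1b (10.8), Ank3 (9.47), Marcks (8.79) and Tubb3 (7.23), which encode proteins of microtubules, the axon initial segment or the actin cortex. At gene ends alone the axon growth call ended (1.96 times, adjusted permutation p = 0.0730, range over its settings 0.0006 to 0.0730). Of 83 axon guidance genes, 47 had a summit (1.47 times, adjusted permutation p = 0.00280). Robo1 (18.3), Ablim1 (10.1), Robo2 (9.81) and Sema3a (8.79) led this list. The axon guidance call ended with peaks of −log10 q of at least 5 (adjusted permutation p = 0.0782), with the stronger part of the list (0.0630) and at gene ends alone (0.667); adjusted p-values over all its settings ran from 0.0006 to 0.667.

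Of 61 synaptic adhesion genes, which encode proteins that join pre- and postsynaptic membranes, 35 had a summit (1.54 times, adjusted permutation p = 0.00472). The strongest were Tenm2 (fold 12.8), Lrrc4c (11.5), Adgrl2 (9.13) and Adgrl3 (9.13). With 50 kb on each side of a gene this call ended (adjusted permutation p = 0.168, range over its settings 0.0006 to 0.168). With length matched more finely, in 200 bins, the list stood at 1.34 times (adjusted permutation p = 0.0341). Of 54 neurodevelopmental disorder genes, 37 had a summit (1.65 times, adjusted permutation p = 0.00084), among them Auts2 (14.5), the basic helix-loop-helix gene Tcf4 (10.5), Satb2 (10.1) and Zbtb20 (9.47). Of 80 cytoplasmic ribosomal protein genes, 33 had a summit (2.57 times, adjusted permutation p = 0.00084), and 29 had it within 1 kb of an end. Without length matching the count was 1.70 times random lists (adjusted permutation p = 0.00344). Rpl30 (9.47), Rps24 (9.13), Rpl21 (8.79) and Rpl35a (8.12) were strongest. The ribosomal excess ended when summits at gene ends were left out (1.09 times, adjusted permutation p = 1.0, range over its settings 0.0006 to 1.0). Of 57 clustered protocadherin genes, which share overlapping annotated bodies, 35 were assigned a summit (1.90 times, adjusted permutation p = 0.00084). These assignments rested on only 2 summits. Pcdhga1, Pcdhga10, Pcdhga11 and Pcdhga12 shared the same summit (fold 5.07), and the list fell below random lists when each summit counted for the nearest gene end (0.169 times, adjusted permutation p = 0.0006, range over its settings 0.0006 to 0.558). Olfactory receptor genes, which are silent in most cells, lay below random lists with 5 of 1105 genes (0.0598 times, adjusted permutation p = 0.00084), including Olfr62 (6.42), Olfr750 (5.75), Olfr15 (4.48) and Olfr459 (4.40). Random lists drew genes singly, so this p-value takes too little spread for genes that lie side by side. The cause of this deficit was not tested.

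**Figure D4:**
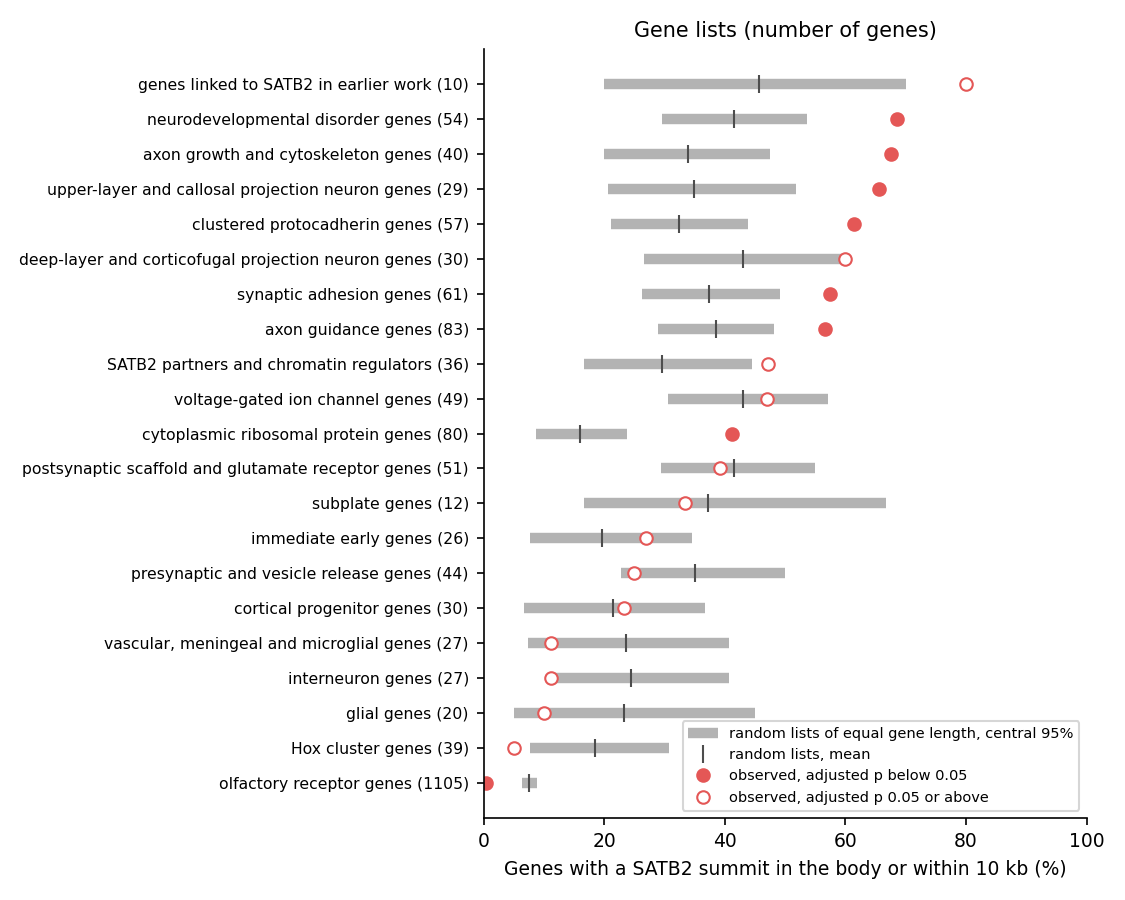
Share of genes with a SATB2 summit in the body or within 10 kb, in percent, for each of 21 gene lists (number of genes in brackets); points are observed shares, filled where the adjusted permutation p is below 0.05, ticks are means and grey bars central 95% ranges of 10000 random lists of equal gene length. Upper-layer genes stand at 65.5% against a random mean of 34.9%, and olfactory receptor genes at 0.452% against 7.57%.

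The remaining lists did not pass. Of 30 deep-layer and corticofugal genes, 18 had a summit (1.40 times, adjusted permutation p = 0.127), led by Diaph3 (fold 10.3), Tle4 (9.50), Cdh18 (8.79) and Ldb2 (8.79). This list passed when summits counted for the nearest gene end (adjusted permutation p = 0.0397), over 1 kb from gene ends (0.0168) and without length matching (0.00105), and its adjusted p-values ran up to 0.742. Of 12 subplate genes, 4 had a summit (0.898 times, adjusted permutation p = 1.0): Hs3st4 (7.82), Kcnab1 (6.76), Unc5c (6.42) and Nr4a2 (3.998). Of 10 genes linked to SATB2 in earlier work, 8 had a summit (1.75 times, adjusted permutation p = 0.0786), with Auts2, Satb2, Sox5 (7.80) and Dcc strongest. This small list passed without length matching (adjusted permutation p = 0.00233), and its adjusted p-values ran up to 0.622. Of 36 SATB2 partners and chromatin regulators, 17 had a summit (1.60 times, adjusted permutation p = 0.0769). The NuRD subunit gene Gatad2b (11.5), the Polycomb gene Eed (9.81), the chromatin remodelling ATPase gene Smarca2 (9.47) and Rcor1 (7.22) were strongest, each at a gene end. That list passed with a −log10 q of at least 5 (adjusted permutation p = 0.0156), on autosomes (0.0336) and without length matching (0.00743), and its adjusted p-values ran up to 1.0.

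Lists of synaptic transmission did not pass either. Of 44 presynaptic genes, 11 had a summit (0.712 times, adjusted permutation p = 0.254), among them Ppfia2 (fold 7.10), Unc13b (6.34), Rims1 (6.09) and Snap25 (6.09). Of 51 postsynaptic scaffold and glutamate receptor genes, 20 had a summit (0.943 times, adjusted permutation p = 0.940), with Grid2 (8.79), Grik5 (8.45), Dlg2 (8.12) and Grm1 (7.44) strongest. Of 49 voltage-gated channel genes, 23 had a summit (1.09 times, adjusted permutation p = 0.765), led by Kcnq5 (10.5), Scn8a (10.1), Kcnn2 (8.79) and Kcnh7 (7.78). Without length matching the postsynaptic list (1.62 times, adjusted permutation p = 0.0369, range over its settings 0.0369 to 1.0) and the channel list (1.94 times, adjusted permutation p = 0.00336, range 0.00336 to 1.0) passed above random lists, and the postsynaptic ratio lay above 1 in 4 of 10 other settings, this one included. Of 26 immediate early genes, 7 had a summit (1.37 times, adjusted permutation p = 0.590), among them Egr2 (7.82), Dusp6 (6.76), Jun (5.67) and Ier2 (5.06).

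Lists of other cell types did not pass. Of 30 cortical progenitor genes, 7 had a summit (1.09 times, adjusted permutation p = 0.988), with Neurog2 (fold 7.92), Ptprz1 (7.10), Dll1 (6.32) and Mfap4 (5.28) strongest. Of 27 interneuron genes, 3 had a summit (0.453 times, adjusted permutation p = 0.205): Erbb4 (8.45), Zeb2 (7.10) and Maf (5.75). Of 20 glial genes, 2 had a summit (0.430 times, adjusted permutation p = 0.315), Aqp4 (5.41) and Mog (3.96). Of 27 vascular, meningeal and microglial genes, 3 had a summit (0.469 times, adjusted permutation p = 0.254), Pecam1 (6.76), Cdh5 (5.91) and Aif1 (5.75). Of 39 Hox cluster genes, which pattern the body axis and hindbrain, 2 were assigned the same summit (0.278 times, adjusted permutation p = 0.0700), Hoxc6 and Hoxc8 (5.41). The ratios of subplate, progenitor, interneuron, glial, presynaptic and immediate early genes crossed 1 in at least 1 other setting without passing. The Hox count passed below random lists in 5 of the 10 other settings, and adjusted permutation p-values ran from 0.00467 to 1.0.

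Some of the strongest summits named for a gene lay outside it, at a neighbour. Those of Mfap4, Aif1, Egr2 and Olfr15 lay within 1 kb of an end of Mapk7, Prrc2a, Ado and Zfp174. Those of Grik5, Mog and Hoxc8 lay inside Atp1a3, Zfp57 and Hoxc6.

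The 20 strongest summits on the assembled chromosomes lay in 18 peaks and had folds of 15.2 to 29.1, and 13 of them were intergenic, 5 were inside genes and 2 lay at gene ends. The strongest peak (chromosome 3, 111488081 to 111489358, 85 reads, exact 95% Poisson interval 67.9 to 105.1) lay 1238 kb from the nearest protein-coding gene end, that of Prmt6. The next were on chromosome 8 (35221609 to 35222662, fold 21.6), 154 kb from Ppp1r3b, and on chromosome 7 (137499869 to 137500974, fold 20.6), 30.9 kb from Glrx3. Robo1 held 2 of the 20 inside its body (folds 18.3 and 16.6), and Ppp2r2b (19.4), Filip1 (17.9) and Cyp7b1 (15.2) held 1 each. The pair at gene ends lay 0.075 kb from Mtpn (17.4) and 0.049 kb from Cops6 (16.9), the latter also within 10 kb of Zfp113 and Mcm7. Tle3 had a summit 1.36 kb from its end (15.6) and was the nearest gene, at 94.2 kb, to another (16.8). The others lay near Gm3415 (20.3 and 19.3), Stmnd1 (19.1), 1700123K08Rik (17.9), Apobec3 (between Filip1 and Mtpn in fold) and Gm5565 (15.6 at each of its 2), or 1608 kb from Tenm2 (16.6).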

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

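Sequences outside the assembled chromosomes, which enter none of the comparisons above, also carried summits that passed the authors' threshold. Mitochondrial DNA carried 23 summits in 3 regions, with a median fold of 2.47 over a median background of 115 reads. Unplaced scaffolds carried 22 summits in 16 regions, with a median fold of 8.79 and a highest fold of 46.7, above the 29.1 reached on the assembled chromosomes.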

How the results depend on the processing

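The tests per gene instead of per Mb, with 2 kb ends, rotated chromosomes, 200 length bins, neighbouring gene ends, autosomes for the lists, merged peaks for clustering and summits over 1 kb from gene ends were chosen after seeing the data. Excesses at gene ends (6.65 to 10.9 times), in gene bodies and in clusters, and the deficit between genes, kept their direction and passed in each setting run. The promoter window of 2 kb upstream, repeat masking, CpG matching, and the settings for GC content and motifs were not run, as they need strand or sequence. Pileups near 17 reads limit each single fold. For the changes below the cause was not tested.

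The X-to-autosome ratio per gene was 0.0840. The strength difference was 0 with −log10 q, where the medians of both classes tied. Genes with a summit numbered 3174 with the stronger part of the list, 2816 at gene ends alone and 8721 with 50 kb. Without length matching 14 lists passed instead of 8.

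Among single lists, ratios to random lists are given. With −log10 q of at least 5, axon guidance (1.34) and clustered protocadherins (1.35) no longer passed, SATB2 partners (1.92) did, and progenitor (0.947) and immediate early genes (0.953) turned direction without passing. With the stronger part of the list, axon guidance (1.42) no longer passed, progenitor genes (0.808) turned without passing, and protocadherins turned to 0. At gene ends alone, axon guidance (1.21) and axon growth (1.96) no longer passed, Hox genes (0) passed below, subplate genes (1.13) turned without passing, and protocadherins (0.124) turned. With the nearest gene end, deep-layer genes (1.49) passed, subplate (1.16), interneuron (1.23) and postsynaptic genes (1.01) turned without passing, and protocadherins (0.169) turned. With 50 kb, synaptic adhesion (1.23) no longer passed, Hox genes (0.479) passed below, and subplate (1.16), presynaptic (1.02) and postsynaptic genes (1.14) turned without passing.

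Without length matching, deep-layer genes (2.49), channels (1.94), SATB2 partners (1.95), genes of earlier SATB2 work (3.30) and Hox genes (0.212, below) passed, postsynaptic genes (1.62) turned and passed, and subplate (1.38), progenitor (0.962) and presynaptic genes (1.03) turned without passing. With 200 length bins, channels (0.988) turned without passing, and no call changed. The ratios of synaptic adhesion (1.34) and neurodevelopmental disorder genes (1.55) fell from 1.54 and 1.65. Upper-layer (1.85), axon growth (1.91), axon guidance (1.42) and ribosomal genes (2.45) also stood lower, and protocadherins (1.93) higher. With neighbouring gene ends matched, Hox genes (0.211) passed below. On autosomes, SATB2 partners (1.69) and Hox genes (0.265, below) passed. With summits over 1 kb from gene ends, deep-layer genes (1.74) passed, ribosomal genes (1.09) and protocadherins (1.29) no longer did, and interneuron (1.17), glial (1.34), postsynaptic (1.11) and Hox genes (1.23) turned without passing. Upper-layer, neurodevelopmental disorder and olfactory receptor genes kept direction and call in all 10 settings.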

Other observations

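The tests of X scarcity, of the 20 strongest summits and of the pooled axon and synaptic lists were chosen after these results were seen. Predictions for the tests of housekeeping families and of gene families by symbol were marked as written beforehand. Neither of those tests was in the original plan. Among 1-Mb windows ranked by their number of SATB2 summits, the window from 83000000 on chromosome 13 held 30 summits and a single protein-coding gene, Mef2c, a transcription factor of neuronal maturation. The window from 49000000 on chromosome 12 held 23 summits and only Foxg1, a regulator of forebrain identity, and that from 56000000 on chromosome 1 held 22 summits with Satb2 and Hsfy2. The window from 69000000 on chromosome 11 held 25 summits among 63 protein-coding genes. Of 3 windows with 18 summits each, the pair on chromosome 16 held only Epha3 or only Usp25, and that from 43000000 on chromosome 10 held 8 genes, among them Sobp, Pdss2 and Bend3. These windows were chosen by their counts.

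Of 184 genes on the axon guidance, axon growth and synaptic adhesion lists, 109 (59.2%) had a summit, against 37.1% for genes of their lengths. Of 144 genes on the presynaptic, postsynaptic and channel lists, 54 (37.5%) had a summit, against 40.1%. The gap of 24.7 percentage points between these excesses is no independent test, because the lists were pooled after it was known which of them passed.

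Gene families were also compared by the stem of their symbols. Of 257 stems with at least 10 genes, 4 lay above random lists of equal gene length and 11 below (adjusted permutation p under 0.05). Rpl, Pcdhga and Pcdha were above and belong mostly to the fixed lists. The calls of Pcdhga and Pcdha do not count separate sites, since all summits assigned to clustered protocadherins came to 2, shared by overlapping genes. Bcl was the 1 stem above that does not, with 13 of 24 genes (2.22 times, adjusted permutation p = 0.0480), among them Bcl11a, Bcl11b, Bcl6 and Bcl9; its members share a symbol and not a common protein family. Below lay Cyp (4 of 99 genes), Krt (1 of 53), Olfr and Vmn (2 of 352), families of cytochromes P450, keratins and odorant or pheromone receptors, with Pramel, Defb, Rhox, Serpinb, Ugt, Prss and Clec. The random lists did not match chromosome, so a family on the X chromosome could fall below through the scarcity of X summits alone. They also drew genes singly, so the p-values take too little spread for families whose genes lie side by side.

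The X chromosome carried 0.0564 times the autosomal density of summits. Fewer genes on the X chromosome cannot account for this, since the ratio per protein-coding gene had an upper 95% limit of 0.117. A lower number of X reads in background and peaks alike, from fewer copies or from reads the aligner did not place, is a candidate explanation: 94.1% of the 34 X summits had a background within 0.001 reads of the lowest level, against 54.8% ± 7.98 (SD) of autosomal summits of equal class and pileup (permutation p = 0.0002, the smallest possible). Thinning autosomal pileups to 50%, as for a single X copy, kept a share of 0.265 of autosomal summits, and thinning to 75%, as for a pool of both sexes, kept 0.744, both above the ratio on the X chromosome, but this takes X sites to be as strong as autosomal ones, so fewer X copies cannot be told apart from other losses as a part of the cause. A filter on the sex chromosomes before deposit, which the sources used here neither give nor exclude, also stays open, and no biological explanation was tested, as the sex of the embryos is not given.

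The 20 strongest summits lay in 18 peaks. Of these summits 13 lay outside protein-coding genes, and 6, in 4 peaks, lay on chromosome 5. Their background had a median of 1.0 times the lowest genome-wide level and a highest value of 1.36 times. None of these summits thus lay over a strongly raised background. Ranking by a fold over background itself favours a low background, so these values do not decide whether copies collapsed in the assembly play a part. Chromatin caught without the antibody's target stays open too, even at folds of 15.2 or more, as there is 1 ChIP library and no control antibody. No biological explanation was tested.

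Ribosomal protein genes were a surprise among targets of a neuronal factor. Counting only summits within 1 kb of their own ends gave 29 of 80 genes. This was 3.60 times random lists (permutation p = 0.0002, the smallest possible). Summits farther off, at neighbours within 10 kb, thus do not account for the excess. A neighbour with an end at the same place is not excluded. The strongest summit of Rpl35a lay within 1 kb of ends of both Rpl35a and Iqcg. The 5 other housekeeping families tested together, 222 genes of the proteasome, mitochondrial ribosome, complex I, translation initiation and chaperonin, had 65 genes with a summit at an end, 2.27 times random lists (adjusted permutation p = 0.000533). Summits at ribosomal genes may therefore be part of a wider capture of open housekeeping promoters whatever the antibody. Binding of SATB2 at active promoters stays equally open, and no biological explanation was tested. By the same measure at gene ends, upper-layer genes stood at 2.28 times, neurodevelopmental disorder genes at 2.17 and synaptic adhesion genes at 2.11. Axon growth genes stood at 1.96 and axon guidance genes at 1.21. With summits over 1 kb from gene ends, upper-layer genes stood at 2.47 times and ribosomal genes at 1.09. With summits in the body or within 10 kb, the 5 other housekeeping families stood at 1.72 times. That was above neurodevelopmental disorder (1.65), synaptic adhesion (1.54) and axon guidance genes (1.47). It was below upper-layer (1.88), clustered protocadherin (1.90), axon growth (1.99) and ribosomal genes (2.57).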
